A study of Liolaemus parthenos with 3 samples.

How the data were processed

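Total RNA of the brain, ovary and liver of 1 adult Liolaemus parthenos, a parthenogenetic lizard, was sequenced as 1 library per tissue, per the labels. The tissues were kept in RNAlater and frozen, RNA was extracted with an RNeasy kit, and the libraries were made with a TruSeq kit without strand information and run on an Illumina HiSeq instrument, per the labels' protocols. Reads from an element and from a gene on the other strand can therefore not be told apart. The stated aim was to try out a pipeline that measures transposable element expression without a reference genome.

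The authors deposited 3 kinds of values. The first is a table of estimated counts per element subfamily, deposited for 31 subfamilies with a column named for each tissue. Its values are sums of fractional read assignments, and 51.6% (Brain column), 71.0% (Ovary column) and 61.3% (Liver column) of them lie within 0.01 of a whole number. The second is a table of log2 CPM for 27 of these subfamilies, deposited by the authors. Base 2 was taken from the values, and the scaling is not given in the sources used here. Its values are not plain CPM: SINE3 in the Liver column corresponds to 1557702 CPM, above the 1000000 that a whole library can hold. Differences of this table between columns are therefore given as those of an unknown scaling. The third is 1 quantification file per sample with estimated counts and TPM for 480 assembled transcripts, in the column layout of Salmon per the file headers, where TPM sums to 1000000 over these transcripts. A further table deposited by the authors gives 1 element name to each of 19207 assembled transcripts and holds no measurement. Bowtie2 2.3.4.1 is named in the submitters' processing notes without a role. The assembler, the repeat annotation and the version of the quantification tool are not given in the sources used here. No genome was used here, so elements carry the names of the files and have no coordinates.

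The columns of the 2 subfamily tables were assigned to samples by their names. The quantification files were assigned through the sample records they are attached to. These sources conflict: the record of the ovary sample carries a file named for the liver, and the record of the liver sample a file named for the ovary. Values from the tables are therefore given by column (Brain, Ovary or Liver column), and values from the files by the tissue of the record ("recorded as ovary"). No value was used to decide between them.

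From the estimated counts, the share of each subfamily in the reads of its library was computed, with an exact Clopper-Pearson 95% interval, and the ratio of shares between 2 libraries with an exact conditional binomial 95% interval on counts rounded to whole reads. Intervals treat reads as independent and cover counting error only. Reads without molecular identifiers are not independent molecules, and uncertainty in the fractional assignment of reads is not covered. The intervals may therefore be too narrow. With 1 library per tissue, no test between tissues was made and no p-value is given. A difference compares 2 libraries, and the spread between animals or between libraries of a tissue is unknown. A subfamily was counted as higher or lower when its ratio was at least 2, both libraries held at least 20 reads together and the interval lay on one side of 1. Deposited log2 CPM and TPM are not counts, so there the ratio and the minimum of reads were used without the interval. Subfamilies short of 20 reads were counted as neither. For brain over ovary, brain over liver and ovary over liver, 28, 28 and 26 of the 31 had enough reads. A count of 0 was set at a floor of 3 reads. The classes and lists were fixed by name: SINE, LINE (with Penelope), LTR (with DIRS and Ngaro), endogenous retroviruses, Gypsy with DIRS and Ngaro, and CR1 with L2. The lists of DNA transposons and rolling-circle elements fixed at the same time are not analysed here, since the 31 subfamilies are retrotransposons, and cell type markers could not be used because the files name no genes. The named subfamilies are the 5 with most reads in each library and, for each pair of libraries, up to 10 on each side that passed the rule, ranked by the interval bound nearest to 1. The 3 transcripts with most reads in each library are named too. These choices and the alternatives were fixed before the data were examined, except the use of the deposited log2 CPM as a scaling, which was added afterwards. The design had foreseen the subfamily sums of the quantification files as a second version of the table. They turned out to cover 16 of the 31 subfamilies and under 1% of the reads, so they serve as a separate data set.

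The depth of the whole libraries is not known from these values. The tables hold reads assigned to elements only: 5468656 in the Brain column, 1143616 in the Ovary column and 1717904 in the Liver column. The quantification files hold 16405 reads for brain, 4651 for the library recorded as ovary and 10644 for the library recorded as liver. At the floor of 3 reads, a count of 0 stands for a share of 5.49e-05%, 0.000262% and 0.000175% in the 3 columns. In the 3 files it stands for 0.0183%, 0.0645% and 0.0282%.

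The alternatives were TMM factors (edgeR 4.0.16) and median-of-ratios size factors (DESeq2 1.42.0), both computed on rounded counts and used for scaling only, a total without the subfamily with most reads, the sums of the quantification files as reads and as TPM, these sums without the top transcript of each library, other minima of reads and of the ratio, and thinning to the smallest total (mean of 100 draws). The top transcripts were all LTR elements and were left out of every file. The interval and the rule were tested on simulated data with 31 subfamilies, the real totals and 8 changed subfamilies per run, in 100 runs. The changed subfamilies were drawn from those other than SINE3, and the noise was counting noise alone. The rates therefore do not cover a change of SINE3 that shifts the total, or the spread between libraries. For brain against ovary, 96.3% of intervals held the true ratio, 87.0% of true 4-fold changes and 38.2% of true 2-fold changes were recovered, and 0.217% of unchanged subfamilies were called beside the 4-fold changes. For brain against liver, 89.8% of 4-fold and 36.9% of 2-fold changes were recovered, and for ovary against liver 85.7% and 35.6%. True 2-fold changes lie at the limit of the rule, so noise leaves many of them below it at any depth. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.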

Results

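Reads assigned to retrotransposons were compared between the brain, the ovary and the liver of 1 adult Liolaemus parthenos, a lizard that reproduces without males, to describe which elements were transcribed in each tissue. The subfamily table held 31 subfamilies: 3 short interspersed elements (SINE), 16 long interspersed elements (LINE, with Penelope) and 12 long terminal repeat elements (LTR, with DIRS and Ngaro). It counted 5468656 reads in the Brain column, 1143616 in the Ovary column and 1717904 in the Liver column. The 3 libraries had no replicates, so intervals give counting error alone, and a difference describes these libraries. The names ovary and liver rest on the column names here, because the sample records attach the quantification files of these tissues the other way round.

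SINE3, the group of SINEs derived from 5S ribosomal RNA genes, dominated every column of the table. It took 91.4% of the reads of the Brain column, 84.3% of the Liver column (95% interval 84.2 to 84.3) and 77.6% of the Ovary column (77.6 to 77.7). In the quantification files, with 3 SINE3 transcripts, it took 0.213% in brain, 0.172% in the library recorded as ovary and 0.395% in that recorded as liver, and reads of 5S ribosomal RNA itself were not told apart from SINE3. CR1, a family of autonomous LINEs widespread in reptiles and birds, came second in all 3 libraries, with 2.63% in the Brain, 5.61% in the Ovary and 7.14% in the Liver column. In the Brain column DIRS, a tyrosine recombinase retrotransposon, followed with 1.37%, then SINE2, the tRNA-derived SINEs, with 0.937% and Gypsy, an LTR retrotransposon, with 0.665%. In the Ovary column DIRS followed with 2.83%, then Pao with 2.49% and Gypsy with 1.99%. In the Liver column ERV2, the betaretrovirus-like endogenous retroviruses, followed with 4.003%, then DIRS with 0.945% and L1, an autonomous LINE, with 0.538%.

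By class, SINEs held 92.4% of reads in the Brain, 79.0% in the Ovary and 84.6% in the Liver column. LINEs held 4.33%, 9.54% and 8.82%, and LTR elements 3.25%, 11.5% and 6.60%. DIRS held 75165 of the 177618 LTR reads in the Brain, 32372 of 131134 in the Ovary and 16238 of 113445 in the Liver column. In the quantification files LINEs led instead, with 66.7% in brain, 64.6% in the library recorded as ovary and 58.2% in that recorded as liver, and SINEs held 0.262%, 0.172% and 0.395%. Outside SINE3, LINEs took 50.5% of the remaining reads in the Brain, 42.7% in the Ovary and 56.2% in the Liver column. LTR elements took 37.9%, 51.3% and 42.0% of them. Because SINE3 sets the total, each ratio of shares was also taken with SINE3 left out, which moved every log2 ratio by 1.38 for brain over ovary, 0.87 for brain over liver and -0.51 for ovary over liver. TMM factors moved them by 1.03, -0.45 and -1.48 and median-of-ratios factors by 0.88, -0.41 and -1.29.

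**Figure D1:**
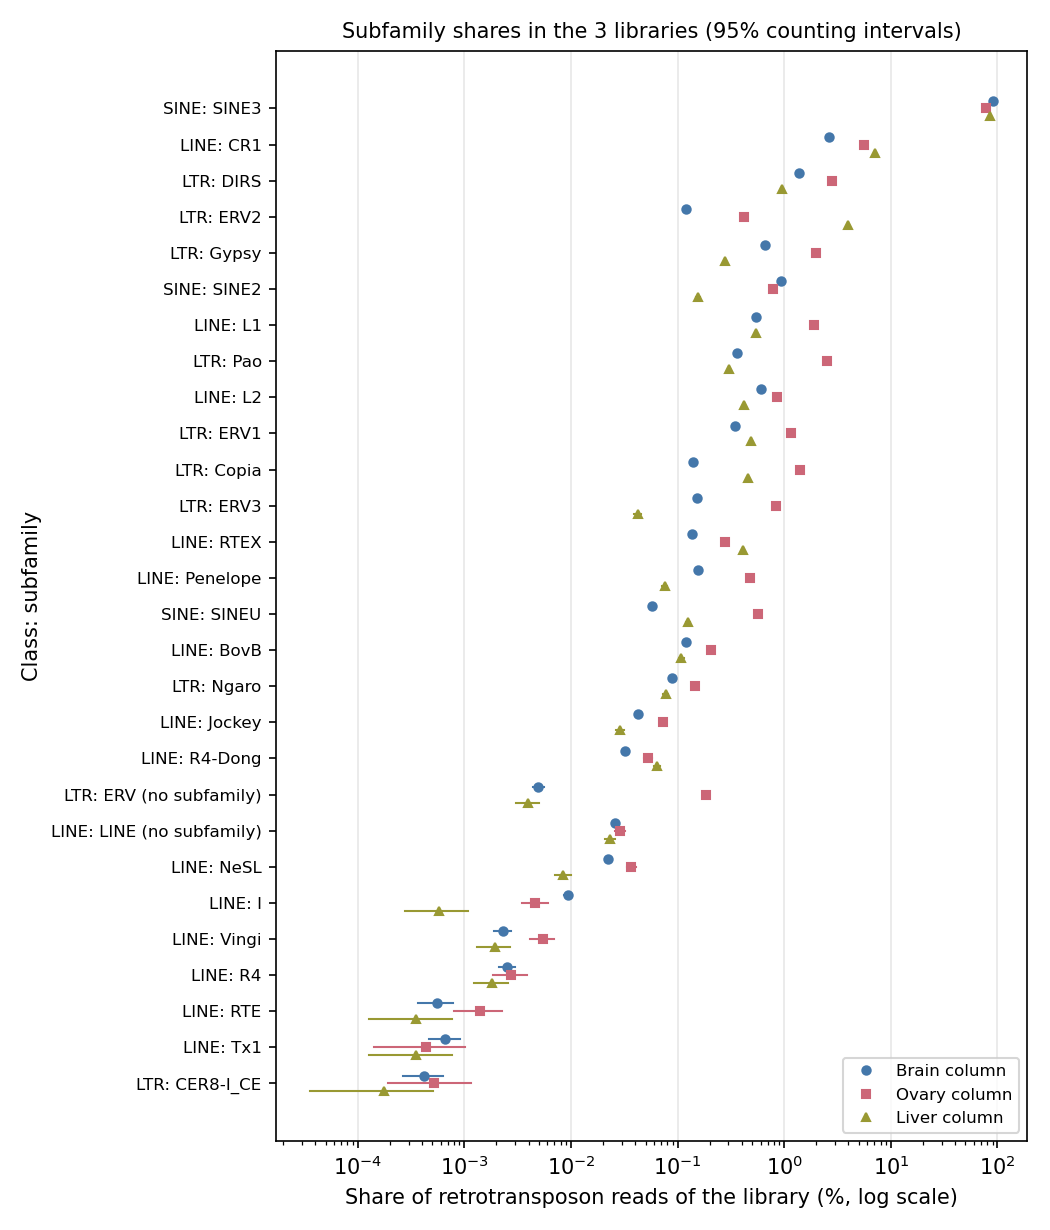
Share of each subfamily in the retrotransposon reads of the Brain, Ovary and Liver columns, in percent on a log scale, for the 28 subfamilies with at least 20 reads over the 3 libraries. Points are 1 library each and lines 95% exact counting intervals. SINE3 lies at 77.6% to 91.4%, CR1 at 2.63% to 7.14%, and ERV2 is spread from 0.121% in the Brain to 4.003% in the Liver column.

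The first comparison asked how brain and ovary differed. LTR elements had a 3.53-fold lower share in the Brain than in the Ovary column (95% interval 3.51 to 3.56), and 8 of the 12 subfamilies were at least 2-fold lower, 0 higher and 4 neither. Without SINE3 the class was 1.35-fold lower, with 4 of the 12 lower. All 4 endogenous retrovirus groups were among the lower ones, and their summed share was 4.17-fold lower (4.101 to 4.231), or 1.60-fold without SINE3, with 2 of the 4 lower. Those named ERV without a subfamily were 36.9-fold lower (32.5 to 42.1; 271 reads in the Brain against 2093 in the Ovary column), and ERV3, the spumavirus-like group, was 5.46-fold lower (5.30 to 5.62). ERV2 was 3.45-fold lower (3.32 to 3.58) and ERV1, the gammaretrovirus-like group, 3.37-fold lower (3.29 to 3.44). The LTR retrotransposons Copia and Pao were 10.1-fold lower (9.83 to 10.4) and 6.98-fold lower (6.86 to 7.11), and Gypsy was 2.99-fold lower (2.94 to 3.04). In the quantification files, the log2 ratio of the LTR class for brain over the library recorded as ovary was -0.094 as reads. As TPM it was -1.93, and without the top transcripts it turned to 0.63. The transcripts left out were themselves all LTR elements, of ERV3 and ERV2. The ERV2 transcript alone held 26.1% of reads in the library recorded as ovary.

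Among the other classes, the SINE group SINEU was 9.99-fold lower in the Brain than in the Ovary column (9.57 to 10.4), L1 3.47-fold lower (3.41 to 3.53) and Penelope 3.07-fold lower (2.96 to 3.17). The I element, a LINE, was the single subfamily past the rule on the other side, 2.04-fold higher in the Brain column (1.53 to 2.75; 516 against 53 reads). These 11 subfamilies kept their direction under all 5 scalings, but without SINE3 Gypsy, L1, Penelope, ERV1 and ERV2 were within 2-fold. In the deposited log2 CPM, ERV without a subfamily differed by -1.64 and Copia by -0.52, against log2 ratios of -5.21 and -3.34. DIRS (2.06-fold lower), CR1 (2.14-fold lower), RTEX, Vingi and RTE were also lower past the rule, and all 5 turned to higher in the Brain column when SINE3 was left out. In all, 1 subfamily was higher and 15 were lower, against 5 and 5 without SINE3, 4 and 5 with TMM or median-of-ratios factors and 3 and 6 in the deposited log2 CPM. The list of CR1 and L2 was 2.002-fold lower (1.98 to 2.02) and that of Gypsy, DIRS and Ngaro 2.33-fold lower (2.31 to 2.36); without SINE3 they were 1.30-fold and 1.12-fold higher. LINEs as a class were 2.20-fold lower (2.19 to 2.22), or 1.18-fold higher without SINE3. SINE2 and SINE3 were 1.21-fold and 1.18-fold higher in the Brain column. Their log2 ratios were 1.30 and 1.27 with TMM factors and 1.15 and 1.12 with median-of-ratios factors, and SINE2 was 3.15-fold higher without SINE3. In the quantification files, which hold far fewer reads, 11 of the 15 subfamilies with reads in both went against the direction in the table between brain and the library recorded as ovary. For 9 of them the counting interval lay beyond 1: ERV3, Gypsy, L1, Penelope, DIRS, NeSL, BovB, Ngaro and L2, all higher in brain. The files held almost no SINE3 reads, so the table without SINE3 is the closer comparison. There DIRS (1.27-fold), NeSL (1.56-fold), BovB (1.54-fold), Ngaro (1.57-fold) and L2 (1.83-fold) were higher in the Brain column too. ERV3, Gypsy, L1 and Penelope stayed lower there.

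Between brain and liver, the share of ERV2 was 33.0-fold lower in the Brain than in the Liver column (32.2 to 33.9; 6624 against 68760 reads), or 18.0-fold without SINE3. Copia was 3.27-fold lower (3.17 to 3.37), RTEX, a LINE of the RTE group, 3.01-fold lower (2.92 to 3.11), CR1 2.72-fold lower (2.70 to 2.74), SINEU 2.19-fold lower (2.07 to 2.32) and R4-Dong 2.01-fold lower (1.86 to 2.17). On the other side, the I element was 16.2-fold higher in the Brain column (8.74 to 34.0, resting on 10 reads in the Liver column) and SINE2 6.03-fold higher (5.80 to 6.27). ERV3 was 3.65-fold higher (3.38 to 3.94), NeSL, a LINE, 2.61-fold higher (2.19 to 3.12), Gypsy 2.39-fold higher (2.32 to 2.47) and Penelope 2.07-fold higher (1.95 to 2.20).

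Of the 31 subfamilies, 6 were thus higher and 6 lower in the Brain than in the Liver column. The direction held under all 5 scalings for each of these except NeSL, whose deposited log2 CPM differed by -0.39 between brain and liver, while that of SINE2 differed by 0.11. Without SINE3, 19 were higher and 1, ERV2, was lower, against 3 and 6 with TMM or median-of-ratios factors and 2 and 3 in the deposited log2 CPM. The 4 endogenous retrovirus groups split, with ERV3 higher, ERV2 lower and ERV1 and ERV without a subfamily within 2-fold; their summed share was 7.28-fold lower in the Brain column (7.19 to 7.38), or 3.98-fold without SINE3, and ERV2 made up 68760 of 78004 reads in the Liver column. Of the Gypsy, DIRS and Ngaro list, 1 of 3 was higher, and the list's share was 1.64-fold higher (1.61 to 1.66), or 2.997-fold higher without SINE3. LTR elements as a class were 2.03-fold lower (2.02 to 2.05), with 2 members higher, 2 lower and 8 neither. Without SINE3 the class was 1.11-fold lower, with 7 higher, 1 lower and 4 neither. LINEs as a class were 2.04-fold lower (2.02 to 2.05), with 3 members higher, 3 lower and 10 neither. Without SINE3 they were 1.11-fold lower, with 11 higher, 0 lower and 5 neither. The abundant DIRS was 1.45-fold higher, SINE3 1.08-fold higher and L1 1.02-fold higher, all under the 2-fold limit. The interval of L1 (0.996 to 1.04) included 1, so its counts gave no direction. The direction for SINE3 turned under TMM and median-of-ratios scaling and in the deposited log2 CPM. The ratio of L1 fell below 1 under TMM and median-of-ratios scaling. In the quantification files, 4 of 15 subfamilies with reads in both, ERV3, NeSL, Penelope and SINE3, had lower shares in brain than in the library recorded as liver, against the direction in the table. LINEs as a class turned there too, with log2 ratios of 0.20 as reads, 0.089 as TPM and 0.16 without the top transcripts.

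Between ovary and liver, 17 subfamilies were higher and 1 was lower in the Ovary than in the Liver column, and 13 and 2 without SINE3. The counts were 6 and 6 with TMM factors, 7 and 5 with median-of-ratios factors and 6 and 5 in the deposited log2 CPM, so their lean to the Ovary column depended on the scaling. ERV without a subfamily was 46.2-fold higher in the Ovary column (36.3 to 59.8; 2093 against 68 reads) and ERV3 19.9-fold higher (18.5 to 21.5). Pao was 8.17-fold higher (7.93 to 8.42), the I element 7.96-fold (4.01 to 17.6; 53 against 10 reads), Gypsy 7.15-fold (6.93 to 7.38) and Penelope 6.35-fold (5.98 to 6.75). SINE2 was 5.001-fold higher (4.79 to 5.22), SINEU 4.56-fold (4.34 to 4.79), NeSL 4.36-fold (3.60 to 5.30) and L1 3.54-fold (3.45 to 3.63). ERV2 alone passed the rule in the other direction, 9.59-fold lower in the Ovary column (9.31 to 9.87).

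Of the 17 higher subfamilies, 12 kept their direction under all 5 scalings, but not their size. In the deposited log2 CPM, ERV without a subfamily differed by 1.08 and SINEU by 0.13, against log2 ratios of 5.53 and 2.19. SINE2, DIRS (2.99-fold higher), ERV1, L2 and Jockey did not, and in the deposited log2 CPM the differences of SINE2 and DIRS between ovary and liver were -0.30 and -0.26. LTR elements as a class were 1.74-fold higher (1.72 to 1.75) in the Ovary column, with 7 of 12 members higher and 1 lower, but lower under TMM and median-of-ratios scaling, with log2 ratios of -0.68 and -0.50. The Gypsy, DIRS and Ngaro list was 3.82-fold higher (3.76 to 3.88), or 2.68-fold without SINE3, and the endogenous retrovirus list 1.75-fold lower (1.73 to 1.77), with 3 members higher and ERV2 lower. Without SINE3 this list was 2.49-fold lower, with 2 members higher, ERV2 lower and ERV1 within 2-fold. CR1 was 1.27-fold and SINE3 1.09-fold lower in the Ovary column. Exchanging the names of the ovary and liver libraries would turn every direction in this comparison, and the sample records do not settle the names. In the quantification files by record, 7 of 15 subfamilies with reads in both went against the table, 4 of them with a counting interval beyond 1: ERV2 was higher, and ERV3, NeSL and Penelope were lower in ovary than in liver.

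**Figure D2:**
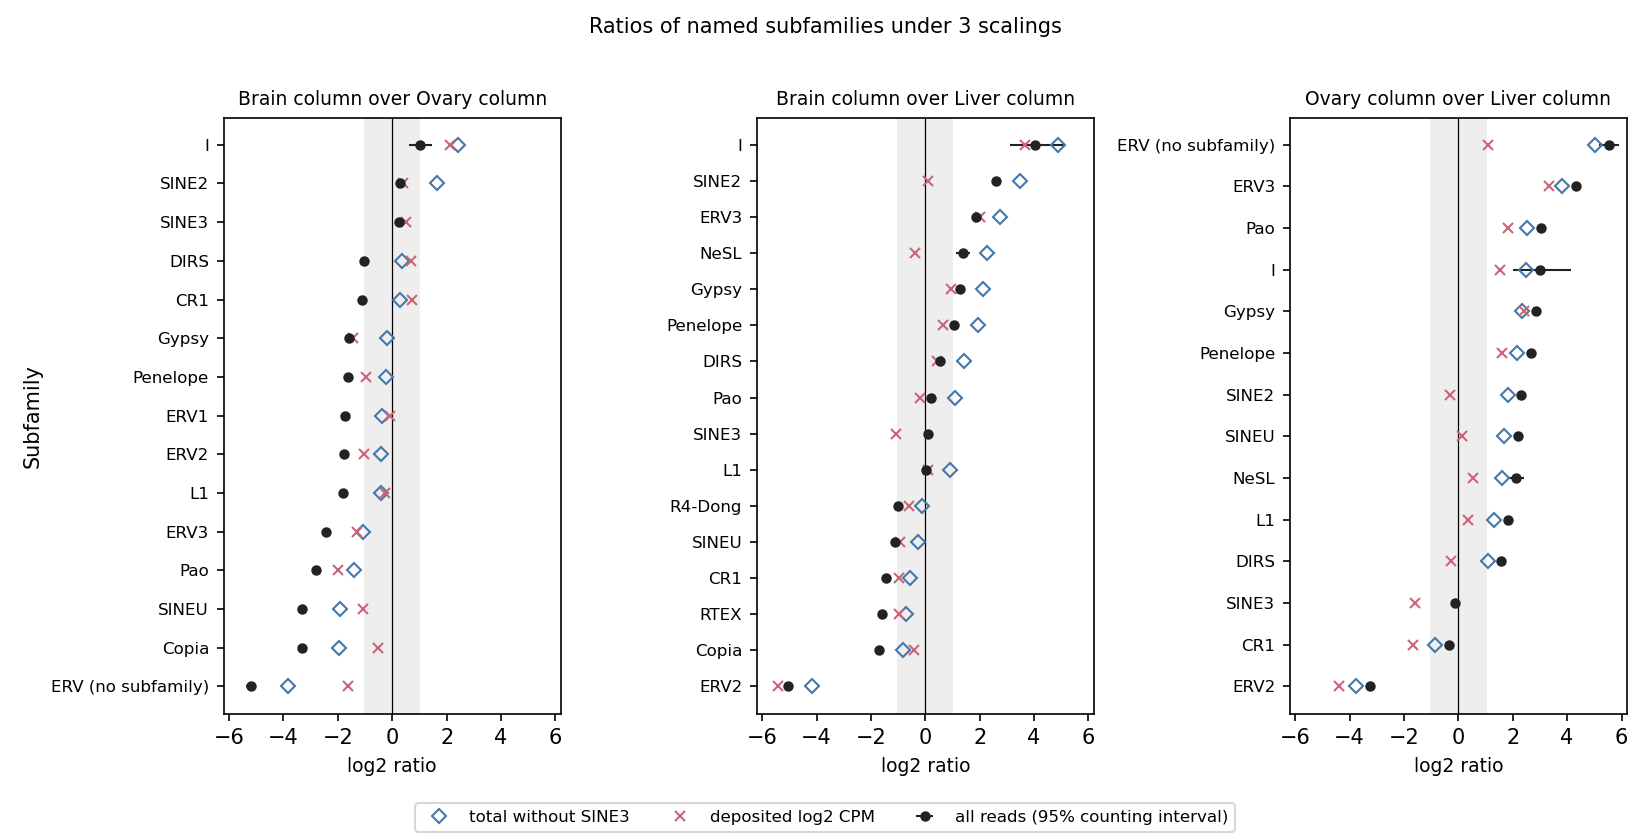
Log2 ratios of the named subfamilies for the 3 pairs of columns, from shares of all reads (black points with 95% counting intervals), from shares without SINE3 (open diamonds) and from the deposited log2 CPM (crosses). The grey band spans less than 2-fold. ERV2 lies left of the band for brain over liver and for ovary over liver under all 3, while DIRS and CR1 cross 0 for brain over ovary.

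Statements on brain against both other libraries hold whichever of these is ovary or liver. The I element was at least 2-fold higher in the Brain column than in both others. Copia, ERV2, CR1, RTEX and SINEU were at least 2-fold lower than in both. With SINE3 left out, 0 of these 5 were 2-fold lower than in both. Higher than in both were 5 subfamilies: the I element, SINE2, R4, Tx1 and LINEs without a subfamily. Tx1 rested on 36 reads in the Brain, 5 in the Ovary and 6 in the Liver column. With all reads, its intervals for brain over ovary (0.589 to 4.92) and brain over liver (0.787 to 5.47) included 1. Its deposited log2 CPM differed by -0.97 for brain over liver. In the quantification files by record, ERV2 was the only one of these 5 at least 2-fold lower than in both, while SINEU had 0 transcripts there. The I element was 1.81-fold higher in brain than in the library recorded as ovary (0.702 to 5.97), on 32 and 5 reads, and its log2 ratio as TPM was -0.12.

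Nearly all subfamilies were detected in each library. At least 1 read was found for 30 subfamilies in the Brain and 31 in the Ovary and Liver columns. The exception, BEL, had 0 of 5468656 reads in the Brain column, against 1 read in the Ovary and 5 in the Liver column. Its exact interval in the Brain column reached up to 6.75e-05%, and the floor of 3 reads stands for 5.49e-05%. The profile without SINE3 was more concentrated in the Liver column, where its effective number of subfamilies was 5.94 and CR1 took 45.5%, than in the Brain (9.95 and 30.6%) and Ovary columns (11.6 and 25.1%). Across the 31 subfamilies, which are not replicates, ranks of shares had a Spearman rho of 0.959 for brain and ovary, 0.924 for ovary and liver and 0.916 for brain and liver. The Bray-Curtis distance was 0.139 (bootstrap interval 0.139 to 0.140) for brain and ovary, 0.0924 for brain and liver and 0.119 for ovary and liver. Without SINE3 it was 0.215 for brain and ovary, below 0.414 for brain and liver and 0.456 for ovary and liver.

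The quantification files held 480 transcripts with a median length of 284 bases, 479 of which carried an element name, in 16 subfamilies. LINEs made up 419 of these, LTR elements 55 and SINEs 5. Reads were found for 445 transcripts in brain, 262 in the library recorded as ovary and 288 in the library recorded as liver, with 186 in all 3. Thinned to 4651 reads each, the numbers were 374 for brain, 262 and 226. The 5 transcripts with most reads took 37.4% of reads in brain, 46.3% in the library recorded as ovary and 50.7% in the library recorded as liver. By TPM, which corrects for length, the top 5 took 14.8%, 42.9% and 23.4%, so the order of the latter libraries turned.

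In brain, an ERV3 transcript of 5332 bases (TRINITY_DN3462_c0_g1_i4) had the most reads, 3638 or 22.2% (21.5 to 22.8), but a TPM of 17267 against 72744 for the shorter CR1 transcript next in reads. It took 1.25% (0.948 to 1.61) in the library recorded as ovary and 10.5% (9.96 to 11.1) in that recorded as liver. Next in brain were a CR1 transcript of 439 bases (TRINITY_DN7542_c1_g2_i3) with 4.80% and another of 3839 bases (TRINITY_DN3590_c0_g1_i1) with 3.60%, which ranked next after the leading transcript in the library recorded as ovary too, with 6.79% and 5.36%. In the library recorded as ovary, the only ERV2 transcript of the files, 588 bases long (TRINITY_DN92387_c2_g2_i2), led with 1214 reads or 26.1% (24.8 to 27.4). It had 9 reads, 0.0549%, in brain and 31 reads, 0.291%, in the library recorded as liver. The library recorded as liver was led by an ERV3 transcript of 3336 bases (TRINITY_DN6071_c0_g1_i1) with 15.1% (14.5 to 15.8) and a CR1 transcript of 7524 bases (TRINITY_DN4126_c0_g1_i2) with 10.96% (10.4 to 11.6). The ERV3 transcript of 5332 bases ranked next there. By TPM, these 3 transcripts lay below the CR1 transcript of 439 bases in this library. Summed over transcripts, ERV3 took 27.1% of reads in brain, 5.96% in the library recorded as ovary and 38.9% in that recorded as liver. ERV2 was thus high in the library recorded as ovary in the files and in the Liver column of the table. Isoforms of 1 assembled component share sequence, so the split of reads among them is uncertain.

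The 19207 named reference transcripts were 64.3% LINE, 32.8% LTR and 2.92% SINE. CR1 had 5758 of them, DIRS 4314, L2 2673 and L1 1524, against 241 for SINE3. Per reference transcript, SINE3 had 20746 reads in the Brain, 3684 in the Ovary and 6009 in the Liver column. CR1 had 24.9, 11.1 and 21.3 reads per reference, and ERV2, with 172 references, had 400 reads per reference in the Liver column. Across subfamilies, the number of references and the number of reads had a Spearman rho of 0.899 in the Brain, 0.868 in the Ovary and 0.872 in the Liver column.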

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

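All tests of explanations in this part were chosen only after the results were seen. A transcript of 201 bases, TRINITY_DN141921_c2_g1_i1, had 6 reads in brain, 0 in the library recorded as ovary and 1 in that recorded as liver. It is the single transcript of the quantification files without an element name in the reference table, so the comparisons do not use it. Its 6 reads lie above the floor of 3 reads in brain. As a share they are 0.0366%, below the 0.0645% of the floor in the library recorded as ovary. A difference from that library was therefore not detectable.

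The quantification files recorded as ovary and as liver differ from the table columns of the same names: without SINE3, the profile of the file recorded as ovary lay at a Bray-Curtis distance of 0.213 from the Liver column and 0.524 from the Ovary column. The brain file, whose names do not conflict, was at 0.481 from its own column and 0.487 from the Liver column, so this distance does not decide whether the smaller reference set of the files is the cause. The file recorded as liver was nearer to the Liver column by this distance (0.476 against 0.543) but had a higher Spearman rho with the Ovary column (0.261 against 0.175). For each of 13 subfamilies, the log2 difference between the libraries in the share of a column's reads held by the file was taken. The median over the subfamilies was subtracted. The mean absolute value was then 1.32 with the 2 files crossed to each other's records, against 2.33 by record. ERV2, 1 transcript in the files, had the largest value by record, 11.1, against 1.61 crossed. After the subtraction, 6 of 13 subfamilies were closer when crossed. The interval of the difference reached from -0.53 to 2.89. It came from resampling the 13 subfamilies, which are not replicates, and so reflects the spread among them only. Both explanations stay open, and no biological explanation was tested.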

How the results depend on the processing

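The alternatives were chosen before the data were examined, except the deposited log2 CPM, which was chosen after seeing the data. Values are log2 ratios of shares, tissue names are those of the columns for the table and of the records for the quantification files, and where not stated otherwise the cause of a change was not tested. No paired analysis was possible because each tissue has 1 library, and for the same reason leaving out a library was not possible. Depth limits the I element (10 reads in the Liver column), Tx1 (5 reads in the Ovary column) and BEL. It also limits the quantification files, with 4651 to 16405 reads. Spearman rho under log2(CPM + 1) was not run, since ranks do not change.

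Of all 46 ratios past the rule, 43 kept their sign under TMM factors, where ERV1, L2 and Jockey for ovary over liver turned, and 44 under median-of-ratios factors, where ERV1 and L2 did. Without SINE3 41 kept it, in the deposited log2 CPM 36, and under all of these 35. Of the 37 that are named, chosen mostly by size, 37 kept their sign under TMM factors and under median-of-ratios factors, 35 without SINE3 in the total and 32 in the deposited log2 CPM. Of those with a value in the quantification files, 13 of 26 kept it as reads, 7 of 26 as TPM and 11 of 23 without the top transcript of each library. Counts of subfamilies were within 1.5 times their value with no minimum of reads, with at least 100 reads and with a ratio of at least 1.5, and counts of subfamilies and transcripts with a read were so after thinning.

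For SINE, LINE and LTR in this order, the reported log2 ratios were 0.23, -1.14 and -1.82 for brain over ovary, 0.13, -1.03 and -1.02 for brain over liver, -0.099, 0.11 and 0.80 for ovary over liver. With TMM factors they were 1.26, -0.11 and -0.79 for brain over ovary, -0.32, -1.48 and -1.47 for brain over liver, -1.58, -1.37 and -0.68 for ovary over liver. Median-of-ratios factors gave 1.11, -0.26 and -0.94 for brain over ovary, -0.28, -1.43 and -1.43 for brain over liver, -1.39, -1.18 and -0.50 for ovary over liver. With SINE3 left out, the ratios were 0.94, 0.24 and -0.44 for brain over ovary, 2.70, -0.15 and -0.15 for brain over liver, 1.75, -0.40 and 0.29 for ovary over liver. These 3 scalings shift all ratios of a pair alike, except that SINE3 itself leaves the SINE class in the last. Sums of the quantification files gave 0.61, 0.047 and -0.094 for brain over ovary, -0.59, 0.20 and -0.33 for brain over liver, -1.20, 0.15 and -0.23 for ovary over liver, their TPM 0.86, 0.34 and -1.93 for brain over ovary, -1.49, 0.089 and -0.58 for brain over liver, -2.35, -0.25 and 1.34 for ovary over liver, and the sums without the top transcripts 0.49, -0.067 and 0.63 for brain over ovary, -0.62, 0.16 and -0.85 for brain over liver, -1.12, 0.23 and -1.47 for ovary over liver.

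Class shares of SINE, LINE and LTR in the quantification files were 0.262%, 66.7% and 33.0% in brain, 0.172%, 64.6% and 35.3% in ovary, 0.395%, 58.2% and 41.4% in liver. As TPM, they were 1.08%, 91.9% and 7.06% in brain, 0.594%, 72.5% and 26.9% in ovary, 3.02%, 86.4% and 10.6% in liver, and without the top transcripts 0.346%, 88.1% and 11.6% in brain, 0.246%, 92.2% and 7.51% in ovary, 0.533%, 78.6% and 20.8% in liver.

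The reported counts of subfamilies at least 2-fold apart were 1 higher and 15 lower for brain over ovary, 6 higher and 6 lower for brain over liver, 17 higher and 1 lower for ovary over liver, 1 higher and 5 lower for brain against both others. With TMM factors there were 4 higher and 5 lower for brain over ovary, 3 higher and 6 lower for brain over liver, 6 higher and 6 lower for ovary over liver, 2 higher and 2 lower for brain against both others. Median-of-ratios factors gave 4 higher and 5 lower for brain over ovary, 3 higher and 6 lower for brain over liver, 7 higher and 5 lower for ovary over liver, 2 higher and 2 lower for brain against both others. Without SINE3 in the total there were 5 higher and 5 lower for brain over ovary, 19 higher and 1 lower for brain over liver, 13 higher and 2 lower for ovary over liver, 5 higher and 0 lower for brain against both others. In the deposited log2 CPM there were 3 higher and 6 lower for brain over ovary, 2 higher and 3 lower for brain over liver, 6 higher and 5 lower for ovary over liver, 1 higher and 1 lower for brain against both others. These counts, and those as TPM below, used no counting interval. In the deposited log2 CPM, 1 of the 3 lower for brain over liver was among the reported 6. The 6 lower for brain over ovary were all among the reported 15, and the 6 higher for ovary over liver among the reported 17. A ratio of at least 4 left 0 higher and 5 lower for brain over ovary, 2 higher and 1 lower for brain over liver, 10 higher and 1 lower for ovary over liver, 0 higher and 0 lower for brain against both others, a stricter rule by construction. Among the 16 subfamilies of the quantification files, as reads, 6 were higher and 1 lower for brain over ovary. There were 6 higher and 2 lower for brain over liver, 1 higher and 4 lower for ovary over liver. For brain against both others, 2 were higher and 1 lower. Often these were not the reported subfamilies. Of the reported 15 lower for brain over ovary, 1 was also lower and 4 were higher as reads. Of the reported 6 higher for brain over liver, 2 were also higher and 1 was lower. Of the reported 6 lower for brain over liver, 1 was also lower and 0 were higher. Of the reported 17 higher for ovary over liver, 0 were also higher and 3 were lower. As TPM there were 6 higher and 1 lower for brain over ovary, 3 higher and 5 lower for brain over liver. For ovary over liver 1 was higher and 6 lower, and for brain against both others 1 higher and 1 lower. Without the top transcripts there were 4 higher and 0 lower for brain over ovary, 6 higher and 2 lower for brain over liver. For ovary over liver 1 was higher and 4 lower, and for brain against both others 2 higher and 0 lower.

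Among named ratios past the rule, those that turned without SINE3 were, for brain over ovary DIRS 0.34, CR1 0.29. In the deposited log2 CPM they were, for brain over ovary DIRS 0.70, CR1 0.71, and for brain over liver NeSL -0.39, and for ovary over liver DIRS -0.26, SINE2 -0.30. Turned in the sums of the quantification files were, for brain over ovary Copia 0.68, DIRS 0.84, ERV3 2.18, Gypsy 1.37, L1 1.21, Penelope 1.21, and for brain over liver ERV3 -0.52, NeSL -0.41, Penelope -1.02, and for ovary over liver ERV2 6.49, ERV3 -2.71, NeSL -2.38, Penelope -2.23. As TPM these were, for brain over ovary Copia 1.29, DIRS 0.60, ERV3 1.90, Gypsy 1.20, CR1 0.21, I -0.12, L1 0.97, Penelope 1.22, and for brain over liver Copia 0.036, ERV3 -1.58, CR1 0.020, NeSL -1.74, Penelope -1.84, and for ovary over liver DIRS -0.46, ERV2 5.70, ERV3 -3.48, L1 -1.01, NeSL -3.45, Penelope -3.06. Without the top transcripts they were, for brain over ovary Copia 0.57, DIRS 0.73, ERV3 0.37, Gypsy 1.26, L1 1.098, Penelope 1.09, and for brain over liver ERV3 -2.23, NeSL -0.45, Penelope -1.05, and for ovary over liver ERV3 -2.60, NeSL -2.29, Penelope -2.15. Among named ratios within 2-fold, those of SINE3, L1 and Pao for brain over liver turned under TMM and median-of-ratios factors. SINE3 and Pao also turned in the deposited log2 CPM (-1.07 and -0.18), and SINE3 in all sums of the files. L1, whose reported interval included 1, turned as TPM too. For ovary over liver, CR1 turned in the file sums with and without the top transcripts (0.020 and 0.10).

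As TPM, the effective number of transcripts and the shares of the top transcript and the top 5 were 227, 7.27% and 14.8% in brain, 60.8, 23.2% and 42.9% in ovary, 113, 6.58% and 23.4% in liver. At least 10 reads were found for 197 transcripts in brain, 53 in the library recorded as ovary and 69 in that recorded as liver, a stricter minimum by construction. Bray-Curtis distances without SINE3 were 0.215 for brain and ovary, 0.414 for brain and liver and 0.456 for ovary and liver, and under log2(CPM + 1) 0.0698, 0.0616 and 0.0887. Spearman rho for brain and ovary was 0.954 without SINE3.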

Other observations

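All tests of explanations in this part, and the assembled components and reference counts below, were chosen only after the results were seen. Summed over the isoforms of a component, the 6 ERV3 transcripts of TRINITY_DN6071_c0_g1 took 28.3% (95% interval 27.5 to 29.2) of reads in the library recorded as liver, 4.89% (4.57 to 5.24) in brain and 4.71% (4.12 to 5.36) in the library recorded as ovary. The 4 CR1 transcripts of TRINITY_DN4126_c0_g1 took 21.7% (20.9 to 22.5) in the library recorded as liver, 12.4% (11.5 to 13.4) in that recorded as ovary and 9.47% (9.03 to 9.93) in brain. Those of another CR1 component, TRINITY_DN3590_c0_g1, lay closer together, at 11.4%, 11.9% and 8.69%. ERV3 had 30 reference transcripts, with 280 reads per reference in the Brain, 320 in the Ovary and 24.1 in the Liver column. The file recorded as liver held 4136 ERV3 reads, more than the 723 of the Liver column and fewer than the 9592 of the Ovary column.

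SINE3 took most reads of each table column but 0.213% of reads in brain in the quantification files, 0.172% in the library recorded as ovary and 0.395% in that recorded as liver. The highest mean was 14 reads per SINE3 reference in a file, against 3684 to 20746 in the table. Reads piled on a few references are a candidate explanation, but the files hold 3 of the 241 SINE3 references, too few to decide. Reads of 5S ribosomal RNA assigned to SINE3 could give the same pattern, and with 0 columns of sequence in the files this stays open. No biological explanation was tested.

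The deposited log2 CPM, in which SINE3 in the Liver column exceeds a whole library at 1557702 CPM, and plain log2 CPM of the count table gave opposite signs for 11 of 27 subfamilies for brain over ovary, 6 for brain over liver and 9 for ovary over liver. The deposited minus the plain value had a median of 0.30 in the Brain, -0.80 in the Ovary and 0.51 in the Liver column. A part shared by the subfamilies of a library is therefore not excluded. As the only difference, a single scaling factor per library is argued against. The deposited minus plain value ranged over at least 1.26 within each library for the 21 subfamilies with at least 100 reads in every library. For these subfamilies, the values have what a factor for each subfamily and library that cancels over the 3 libraries needs. The largest absolute sum over the libraries was 0.0065 among them. Among subfamilies with fewer reads, the sum reached 0.34 for Tx1. Offsets from transcript length are one way such factors may arise, which was not tested. No biological explanation was tested.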
